A study of Caenorhabditis elegans with 2 samples.

How the data were processed

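The series measured where a CEH-40 fusion protein sits on the genome of whole young adult worms, 76 h old, by ChIP-seq with an antibody against GFP after sonication, in 2 biological replicates of 1 strain. Per the labels, the strain carries a ceh-40 transgene with a tag of TY1, EGFP and FLAG and a copy of unc-119 that rescues an unc-119 mutation. Per the file headers, coordinates are on genome build ce11. The aligner, the peak caller and their versions are not given in the sources used here. There is 1 group, so no comparison between conditions was made.

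The authors deposited peak lists at several levels: a ranked and a thresholded list for each replicate, and ranked, thresholded and conservative lists made from both replicates. Ranked lists order peaks by the irreproducible discovery rate (IDR), a measure of how well the ranks of matched peaks agree between a pair of peak sets. The deposited column of -log10 IDR reaches 5, and each deposited score follows it. Thresholded lists end at an IDR of 0.01, read from the lowest deposited score and -log10 IDR in them. For the thresholded lists, the descriptions deposited with the samples name 1 more input than for the ranked lists. Each peak's signal value is the authors' own, deposited with no stated unit, and was used only to describe, rank or filter peaks within a list. The ranked list of both replicates also holds the signal of the matched peak in each replicate: its first signal column had 33732 exact matches in the ranked list of replicate 1 and 0 in that of replicate 2, and its second had 37661 in that of replicate 2 and 0 in that of replicate 1. The lists hold no read counts, so the depth per sample is unknown. Other kinds of file, such as signal tracks and alignments, were not analysed here.

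Genes and transcription start sites came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence, gene names missing or shared in Ensembl, and tRNA isotypes came from the RefSeq annotation of that assembly through the shared gene IDs, or by position on the mitochondrial genome. Coordinates are 1-based. Each summit was assigned to the nearest TSS of any gene. A gene counted as having a peak when a summit of the pooled thresholded list was within 1 kb of any of its start sites. Summits were placed in the first that applied of noncoding RNA exon, UTR, coding sequence, other exon, intron and intergenic sequence. Small RNA genes are here those annotated as tRNA, snoRNA, snRNA or rRNA.

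Tests were chosen before the data were examined. Overlap and distance shares were compared with 10000 random placements within each chromosome (permutation p, two-sided, smallest value 0.0002). The share on X was compared with its share of the nuclear genome by an exact binomial test. The 26 gene lists were tested with Fisher's exact test, protein-coding lists against other protein-coding genes and noncoding classes against all other genes, and 4 of the symbols in the list of other homeobox genes were not found in the annotation (83 found). Sites were searched on both strands in 200 bp around each summit and in 200 bp centred 500 bp away, and compared with an exact McNemar test; 1 mitochondrial summit had no full window. 6-mers used a one-sided Fisher test, which did not use the pairing of each summit window with its control window. Families of tests were adjusted by Benjamini-Hochberg with a threshold of 0.05. These p-values take peaks or genes as units, not replicates, and neighbouring peaks and genes are not independent. Intervals are Wilson 95% intervals and cover counting error only.

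The genes named in the text follow a rule fixed before the data were examined: the 20 peaks of highest signal that overlap a conservative peak, all members of the Hox, TALE, vitellogenin and PBC-Hox target lists with ceh-40 and unc-119, up to 4 members of highest signal in each other list, and the 3 strongest peaks of each replicate list with no match in the other. Under that rule the tRNA list gives only mitochondrial genes, tRNA-Ile, tRNA-Arg, tRNA-Gln and tRNA-Phe, which share 1 peak (signal 3541), so nuclear tRNA genes were also named, after their values were seen. Genes named outside the rule are marked as such.

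Alternatives fixed beforehand were other windows, overlaps and controls, the conservative list, an IDR of at most 0.01, and each replicate's own list in place of the pooled one. The IDR of at most 0.01 moved nothing, since the lists already end there, and a limit of 0.001 was added after the data were seen, together with sets without mitochondrial summits or without summits near small RNA genes. The computations were tested on simulated peaks with known answers at the size of the real lists. With 840 random peaks, the site test called 6 of 100 sets with nothing planted and 100 of 100 with the site planted in 20% of windows, the TSS test 8 and 100 of 100, and the gene list test 1 and 100 of 100. The 6-mer test called 1 6-mer over 10 sets with nothing planted and found the planted 6-mer in 10 of 10, and the overlap test on 280 peaks called 0 of 20 sets and then 20 of 20. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.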

Results

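Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole young adult Caenorhabditis elegans at 76 h of age. The worms carried a transgene that expresses CEH-40, a homeodomain protein of the PBC class of Hox cofactors, fused to green fluorescent protein (GFP) and to the TY1 and FLAG tags. Chromatin was pulled down with an antibody against GFP. There was 1 group with 2 biological replicates, so the design compares replicate with replicate, and bound regions with the rest of the genome. The authors' thresholded list made from both replicates (the pooled list) held 867 peaks, of which 840 lay on the nuclear chromosomes and 27 on the mitochondrial genome. Their conservative list held 713 peaks, and the lists of replicate 1 and replicate 2 held 296 and 287. The peak lists carry no read counts, so the sequencing depth behind each peak is unknown. Each peak has a signal value given by the authors, with no stated unit, which is used here to rank peaks within a list.

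Genes for small structured RNAs were among those most enriched for peaks, although 538 of the 840 nuclear summits lay away from them. Of 634 tRNA genes, 298 (47%) had a summit within 1 kb of their transcription start site (TSS), against 2.46% of all other genes. Among small nucleolar RNA (snoRNA) genes, which guide the modification of ribosomal RNA, 68 of 346 (19.7%) had one, and among small nuclear RNA (snRNA) genes, which serve in splicing, 21 of 129 (16.3%). On the nuclear chromosomes alone, 276 of 612 tRNA genes had a peak (45.1%, Wilson 95% interval 41.2 to 49.1). None of the 20 nuclear ribosomal RNA genes had a peak of the pooled list, but 4 of the 20 had a ranked peak past the same threshold that this list does not hold. Altogether 302 of the 840 nuclear summits (36%, 32.8 to 39.3) were within 1 kb of a tRNA, snoRNA, snRNA or rRNA gene, which is 18.2 times the 1.97% of random positions. Of the 216 summits within 1 kb of the start of a nuclear tRNA gene, 150 (69.4%) lay inside a tRNA gene. Of the same 216 summits, 204 were within 100 bp of the start, and the median offset was 20.5 bp into the gene. The snoRNA summits had a median offset of -34.5 bp, on the upstream side.

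Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 26 gene lists fixed before the data were examined, gave an odds ratio of 35.1 for tRNA genes (adjusted p = 5.07e-279), 8.07 for snoRNA genes (adjusted p = 1.53e-33) and 6.22 for snRNA genes (adjusted p = 2.35e-09). In the list of replicate 1 alone 102 of the 612 nuclear tRNA genes had a peak, and in that of replicate 2 alone 113. The snoRNA genes had a peak at 40 of 346 (11.6%) and 41 of 346 (11.8%) in these lists. The snRNA genes did not pass in the list of replicate 2 (5 of 129, Fisher's exact adjusted p = 0.0657). Genes are the units of these tests, and neighbouring genes can share 1 peak, since the 298 tRNA genes were reached by 239 peaks.

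**Figure D1:**
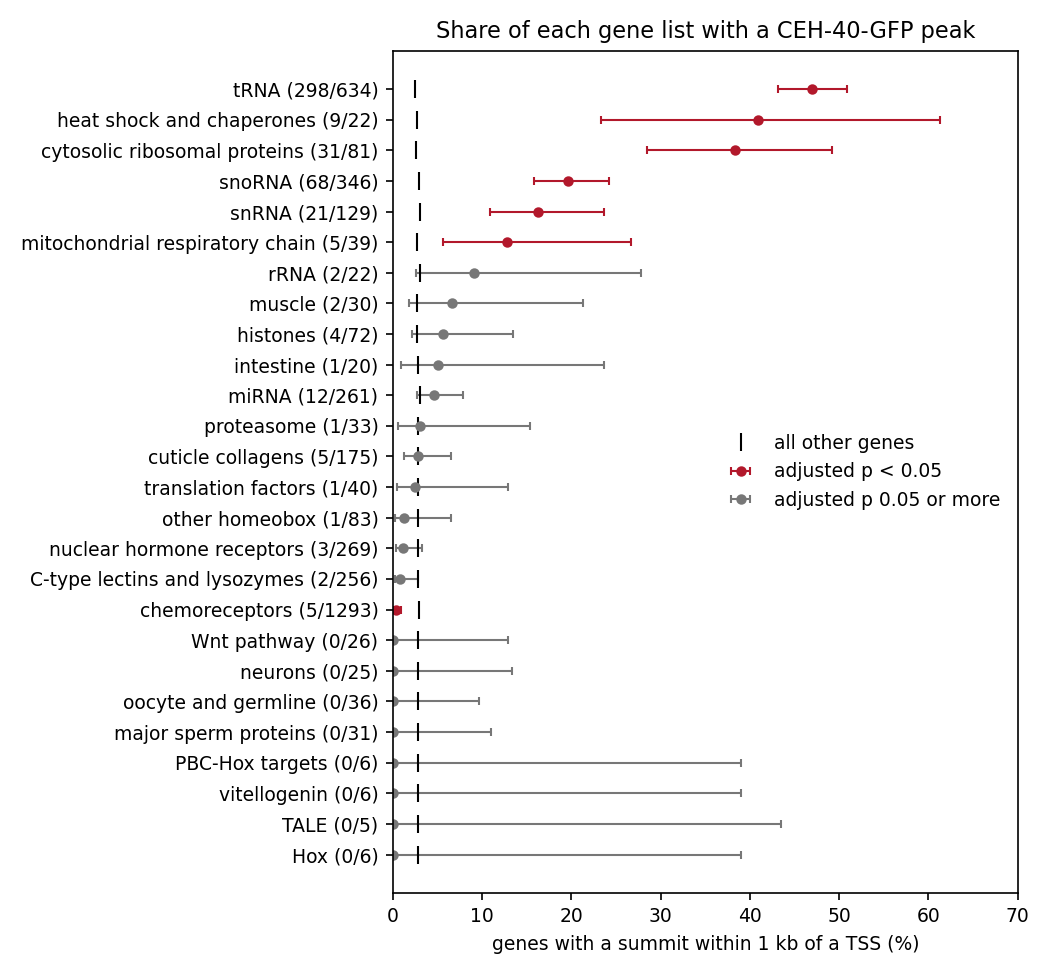
Share of the genes of each list, in percent, with a summit of the pooled list within 1 kb of a TSS. Points are the shares, bars are Wilson 95% intervals, and red marks lists past the adjusted threshold. Vertical ticks are the shares of other protein-coding genes for the protein-coding lists and of all other genes for the noncoding classes. tRNA genes (47%), heat shock genes (40.9%) and ribosomal protein genes (38.3%) lie far to the right of the other genes, and chemoreceptor genes (0.387%) lie to their left.

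The strongest nuclear peaks included several at genes for nucleolar and RNA-processing RNAs. The snoRNA gene ZK994.7 had the second strongest nuclear signal of the pooled list, 351.5, at chromosome V 8500469 to 8500648 in an intron, with 193.4 in replicate 1 and 154.4 in replicate 2. Other snoRNA genes followed with C51F7.4 (signal 266.2, V 12303580 to 12303711), which shares its peak with C51F7.3, and T03F7.8 (signal 245.0, V 11314130 to 11314274). The gene rpr-1, which encodes the RNA of RNase P, the enzyme that trims tRNA precursors, had a signal of 210.5 at I 13463910 to 13463997, 9 bp from its start. The RNase MRP RNA gene mrpr-1 had a signal of 105.8 at II 7200124 to 7200363, 11 bp from its start. These last genes were named after their values were seen. Among nuclear tRNA genes, also chosen after the values were seen, the highest signals were 146.2 at the tRNA-Leu gene C04A11.t1 (X 13665483 to 13665722), 144.3 at the tRNA-Thr gene R01H5.t1 (X 12563678 to 12563917) and 141.5 at the tRNA-Lys gene K11E4.t5 (X 13730250 to 13730489). Of the snRNA genes, sls-2.4, which encodes a spliced leader RNA, had the highest signal (139.8, I 4172269 to 4172374), followed by F54D8.7 (106.6), W05B2.8 (95) and sup-6 (94.8). The summit of the sls-2.4 peak was past the end of that gene, 122 bp from its start and 22 bp from the start of the noncoding RNA gene R12E2.18.

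**Figure D2:**
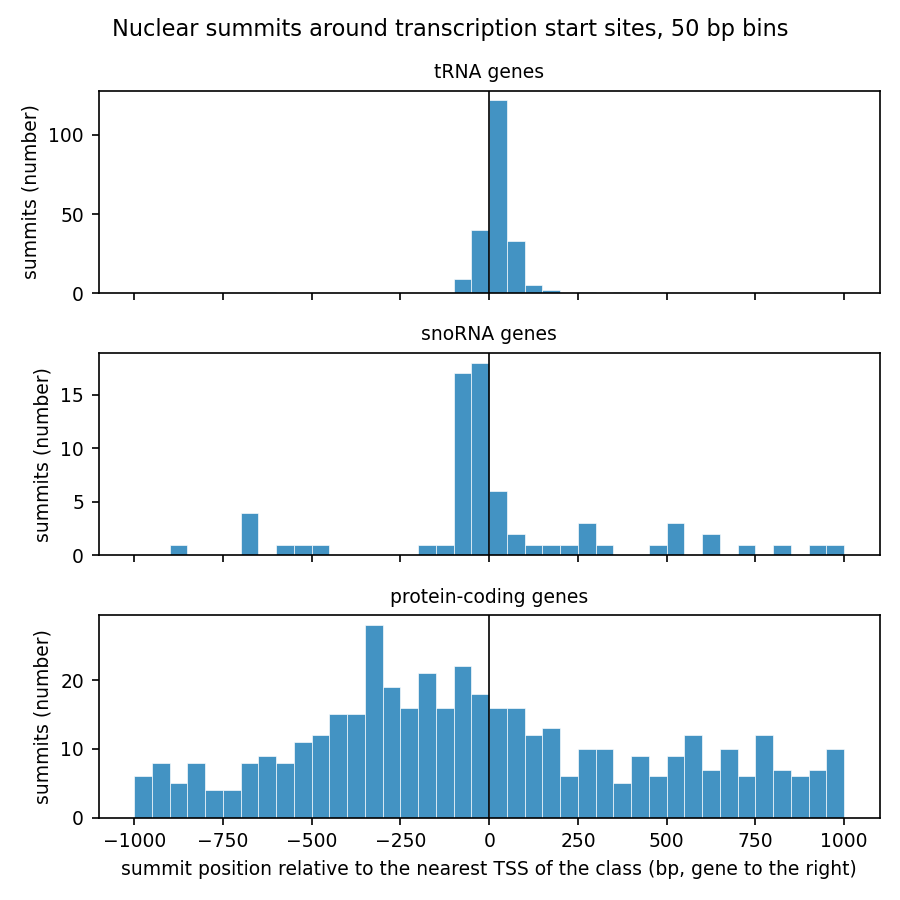
Number of nuclear summits of the pooled list in 50 bp bins by their position relative to the nearest tRNA, snoRNA or protein-coding TSS, in bp, with the gene to the right of 0. The tRNA summits pile up just inside the gene (median 20.5 bp), the snoRNA summits just upstream (median -34.5 bp), and the protein-coding summits spread widely around a median of -78 bp.

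Among protein-coding genes, peaks gathered at ribosomal protein and heat shock genes and were scarce at chemoreceptor genes. Of 81 cytosolic ribosomal protein genes, 31 (38.3%, 28.4 to 49.2) had a peak, against 2.61% of the other protein-coding genes. The strongest was at rpl-3 (signal 225.9, III 3867523 to 3867652, intergenic, 285 bp upstream of the TSS), followed by rpl-15 (148.1, IV 654800 to 655039, 559 bp from the start of the snoRNA gene K11H12.13), rpl-35 (144.0, III 7854570 to 7854809) and rpl-20 (138.8, IV 4749958 to 4750197). The rpl-35 peak was in the list of replicate 1 but neither in that of replicate 2 nor in the conservative list. Ribosomal protein genes had a peak at 16 of 81 (19.8%) in the list of replicate 1 and at 11 of 81 (13.6%) in that of replicate 2. Of 22 heat shock genes, 9 had a peak (40.9%, 23.3 to 61.3), but 3 of 22 (13.6%) had one within 500 bp of the start. The gene hsp-1, an HSP70 chaperone, had a signal of 90.5 at IV 17278887 to 17279126. The genes hsp-16.48 and hsp-16.49, which encode small heat shock proteins, shared a peak of signal 81.9 at V 9088867 to 9089106. Its summit lay between the genes, past the end of each, 856 and 779 bp from their starts. The gene hsp-3 had 68.4 at X 6092067 to 6092306. Chemoreceptor genes, which sensory neurons use to detect odours, had a peak at 5 of 1293 members (0.387%, 0.165 to 0.902), against 2.92% of other protein-coding genes. The strongest were sre-23 (150.1, in the list of replicate 1 but neither in that of replicate 2 nor in the conservative list), srd-44 (84.6), srv-16 (70.8) and srx-29 (56.5). The peaks of sre-23, srd-44 and srv-16 lay 60, 28 and 50 bp from the starts of the snoRNA gene ZK265.10 and the tRNA genes F17A2.t1 and Y105C5B.t2.

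By the same Fisher's exact test, ribosomal protein genes had an odds ratio of 23.2 (adjusted p = 1.03e-26), heat shock genes 24.9 (adjusted p = 1.33e-08) and chemoreceptor genes 0.129 (adjusted p = 6.28e-10). Genes of the mitochondrial respiratory chain passed with 5 of 39 (12.8%, Fisher's exact adjusted p = 0.0153), among them cox-6A (signal 106.6, the peak of the snRNA gene F54D8.7, with its summit 837 bp from the cox-6A start), cox-5A (81.3), cyc-2.1 (67.7) and atp-3 (57.8). That call ended when summits were placed at random with their chromosome and TSS distance kept (permutation test, adjusted p = 0.275), and by Fisher's exact test in the lists of replicate 2 (adjusted p = 0.138) and replicate 1 (0 of 39). The heat shock call ended in the list of replicate 1 (2 of 22, Fisher's exact adjusted p = 0.0740). At an IDR of at most 0.001, a limit chosen after the data were seen, the calls for heat shock genes (1 of 22, Fisher's exact adjusted p = 0.392), the respiratory chain (2 of 39, adjusted p = 0.102) and chemoreceptors (2 of 1293, adjusted p = 0.0648) all ended. Many snoRNA and tRNA genes lie close to protein-coding genes, so the test was repeated without summits within 1 kb of a small RNA gene and without genes that have one within 2 kb, a choice made after the data were seen. Ribosomal protein genes (25 of 61, 41%, adjusted p = 6.46e-26), heat shock genes (4 of 16, 25%, adjusted p = 0.00146) and the respiratory chain (4 of 36, 11.1%, adjusted p = 0.0262) were still above other genes by Fisher's exact test.

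The pooled list had no peak within 1 kb of the starts of the genes that a Hox cofactor is best known for. None of the 6 Hox genes (ceh-13, lin-39, mab-5, egl-5, php-3 and nob-1), the 5 genes of the TALE class to which CEH-40 belongs (ceh-20, ceh-40, ceh-60, unc-62 and psa-3), the 6 vitellogenin genes (vit-1 to vit-6), which encode yolk proteins, or the 6 genes known to be regulated by PBC and Hox proteins (hlh-8, egl-1, psa-3, egl-18, ceh-13 and lin-39) had a summit of the pooled list within 1 kb. The list of replicate 2 had 1, at ceh-40 itself (X 12320801 to 12321030, signal 30.7, 139 bp from the start), a locus that the transgene copies. Counts of 0 among 6 and 5 genes allow shares of up to 50% and 60% (3 counts of the total), so these lists cannot show a lack of binding (Fisher's exact adjusted p = 1 for each). A window of 2 kb gave no peak of the pooled list at these genes either. Apart from the surroundings of ceh-40, sequence farther from the starts, which includes parts of the longer genes, was not searched. In the ranked list of all candidate peaks, the strongest signal within 1 kb of a TSS among Hox genes was 39.7 at nob-1, 37.2 at ceh-13, 30.7 at egl-5, 24.0 at lin-39, 23.9 at mab-5 and 17.5 at php-3. Among TALE genes it was 41.4 at ceh-40, 36.6 at unc-62, 31.2 at ceh-60 and 22.5 at psa-3, with no ranked peak at ceh-20. The vitellogenin genes had 35.9 at vit-4, 29.1 at vit-2, 26.6 at vit-6, 26.6 at vit-3, and 24.7 at both vit-1 and vit-5, and the other known targets had 29.1 at egl-1, 26 at hlh-8 and 22.7 at egl-18. The median over protein-coding genes was 25. The list medians of 27.4 (Hox), 31.2 (TALE), 26.6 (vitellogenin) and 25 (known targets) did not differ from random gene lists of the same size in a permutation test (adjusted p = 0.789, 0.398, 0.870 and 0.997).

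The remaining lists did not pass the threshold in the Fisher test. They were other homeobox genes (1 of 83, ceh-2), nuclear hormone receptors (3 of 269, nhr-58, nhr-211 and nhr-255), translation factors (1 of 40, iff-2), the proteasome (1 of 33, rpn-3), histones (4 of 72, his-59 to his-62, by 3 peaks), cuticle collagens (5 of 175, led by col-52 with a signal of 119.2, then col-85, col-185 and col-42), muscle genes (2 of 30, unc-60 and act-2), intestinal genes (1 of 20, end-3), and C-type lectins and lysozymes (2 of 256, clec-196 and clec-57). Of these peaks, those of ceh-2, nhr-255, col-85 and col-185 had the start of a tRNA gene within 25 bp, that of clec-57 the start of an snRNA gene at 7 bp and that of iff-2 the start of a snoRNA gene at 682 bp. The summit of the clec-196 peak was past the end of that gene, 951 bp from its start, and lay upstream of hsp-1. With a TSS window of 2 kb, C-type lectins and lysozymes passed with fewer peaks than other genes (4 of 256, 1.56% against 4.60%, Fisher's exact adjusted p = 0.0491). No member of the lists of major sperm proteins (31 genes), oocyte and germline genes (36), neuronal genes (25) or the Wnt pathway (26) had a peak within 1 kb. Of the microRNA genes 12 of 261 had one (4.60%, Fisher's exact adjusted p = 0.320), with mir-51 first (signal 138.0) and mir-54, mir-55 and mir-56 sharing another (73.5). Of the ribosomal RNA genes 2 of 22 had one, both mitochondrial. When the strongest signal within 1 kb in the ranked list was compared in place of thresholded peaks, 11 lists were above random lists of the same size (permutation test). These were the 6 of the Fisher test and also, by permutation, translation factors (median 33.2, adjusted p = 0.0013), the proteasome (33.9, adjusted p = 0.0013), cuticle collagens (29.2), oocyte and germline genes (36) and microRNAs (26), the last 3 at an adjusted p of 0.00052.

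Peaks were close to transcription start sites. Of the 867 summits, 572 (66.0%, 62.8 to 69.1) were within 500 bp of an annotated TSS of any gene, against 35.3% of random positions (permutation p = 0.0002, the smallest that 10000 placements can give). Start sites of protein-coding genes alone accounted for 34.8%, against 24.2% of random positions. Exons of noncoding RNA held 221 of the 840 nuclear summits (26.3%), which is 19.6 times the random share of 1.34%. Coding sequence (13.2% against 24.1%) and introns (16.3% against 32.9%) held fewer summits than random positions and intergenic sequence about as many (37.3% against 36.7%). Without mitochondrial summits and those within 1 kb of small RNA genes, a choice made after the data were seen, 47.6% of the 538 remaining summits were within 500 bp of a TSS, against 34.1% of random positions (permutation p = 0.0002). The 434 peaks of higher signal lay near a TSS more often than the 433 of lower signal, 73.3% against 58.7%, a difference of 14.6 points (Fisher's exact test, p = 6.09e-06). By the same exact test, that difference was no longer past the threshold in the lists of replicate 1 (6.76 points, p = 0.249) and replicate 2 (2.30 points, p = 0.699), with a window of 1000 bp (3.74 points, p = 0.181), or without mitochondrial summits and those near small RNA genes (1.49 points, p = 0.796).

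Chromosome X carried more peaks than its length predicts, and these were peaks at tRNA genes. X held 195 of the 840 nuclear summits (23.2%, 20.5 to 26.2), against 17.7% of the nuclear genome (exact binomial test, p = 4.53e-05). The share was also above the 13.7% expected from protein-coding genes (exact binomial p = 9.03e-14). X also holds 276 of the 612 nuclear tRNA genes (45.1%), and 121 of its 195 summits were within 1 kb of a tRNA gene. Of the tRNA genes on X 156 of 276 (56.5%) had a peak, against 120 of 336 (35.7%) on the other nuclear chromosomes (Fisher's exact test, p = 3.78e-07, chosen after the data were seen). Without the summits near tRNA genes, a choice made after the data were seen, the direction against length turned: X held 74 of 624 (11.9%, 9.55 to 14.6), fewer than its length predicts (exact binomial p = 7.95e-05). That interval includes the 13.7% expected from protein-coding genes, so no shortfall was shown against gene content. On that count X had 4.18 summits per Mb, chromosome V had 4.78, and chromosomes I to IV had 6.87 to 8.20.

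**Figure D3:**
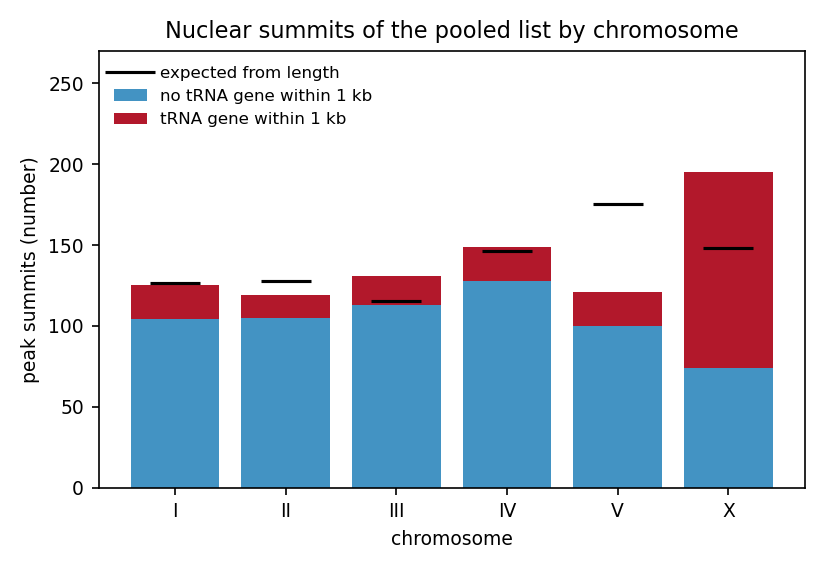
Number of nuclear summits of the pooled list per chromosome, split into those with (red) and without (blue) a tRNA gene within 1 kb, and the number expected from chromosome length (black lines). X has 121 summits near tRNA genes and 74 others, where 148.4 in all would follow from its length, and each other chromosome has 14 to 21 near tRNA genes.

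The sequence bound by PBC and Hox homeodomain pairs was not enriched at the summits. The site TGATNNAT occurred in 70 of 866 windows of 200 bp around summits (8.08%, 6.45 to 10.1), fewer than the 14% of windows 500 bp away (exact McNemar test, p = 8.81e-05). Summit windows had a higher GC content, 43.4% ± 7.55 (SD over windows), than the flanking windows with 37.2% ± 7.89. Against summit sequences shuffled with their dinucleotides kept (9.82%) the shortfall did not pass (exact McNemar p = 0.218). It did not pass either in the shorter lists of replicate 2 (8.74% of 286 windows against 12.9% of flanks, exact p = 0.134) and replicate 1 (10.5% of 295 against 15.6%, exact p = 0.0722). By the exact McNemar test adjusted over 11 sites, the related composite PBC-MEIS site TGATTGACAG occurred in no window, the MEIS site TGACAG in 7.04% against 5.54% of flanks (adjusted p = 0.332), the sequence TGATTGAT in 0.693% against 1.15% (adjusted p = 0.556), and the Hox core TAATTA in 5.54% against 12% (adjusted p = 2.05e-05, fewer).

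The sequence most enriched at summits was that of tRNA genes. The B box GGTTCGANNCC, the internal promoter element that RNA polymerase III uses at tRNA genes, occurred in 141 of the 866 summit windows (16.3%) against 0.924% of flanks (adjusted p = 1.41e-35, exact McNemar test over 11 sites). The GC box GGGCGG was also more frequent (8.78% against 3.70%, exact McNemar adjusted p = 2.78e-05), while runs of T (11.3% against 19.6%, adjusted p = 1.60e-05) and GATA sites (26.7% against 32%, adjusted p = 0.0278) were less frequent. E-boxes (4.39% against 3.93%) and GA repeats (2.89% against 1.5%) did not pass. Against shuffled summit sequences, the B box alone among the 11 sites passed. Without mitochondrial summits and those near small RNA genes, the B box was in 1.86% of 538 windows against 0.372% of flanks (exact McNemar adjusted p = 0.0238). Its excess therefore lay mostly at summits near small RNA genes and is not evidence apart from the peaks at tRNA genes. In an unbiased search of 2080 6-mers, 335 were enriched at summits (one-sided Fisher test, adjusted over the 6-mers), led by CGAACC (21.4% against 3.0%) and GTTCGA (25.6% against 7.39%), both parts of the B box. By the same Fisher's exact test, 93 passed against shuffled sequences, of which 58 were among the 335. Without mitochondrial summits and those near small RNA genes 77 passed, of which 66 were among the 335. CGCGCA was first there (14.1% of 538 windows against 2.79%, Fisher's exact adjusted p = 8.77e-09).

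Within the pooled list, the mitochondrial genome carried the highest signals. Its 27 peaks covered 43.4% of its 13794 bp, against 0.198% of the nuclear genome covered by the nuclear peaks, and had a median signal of 461.7, which is 6.84 times the nuclear median of 67.5. Of the 20 strongest peaks of that list that overlap a peak of the conservative list, 18 were mitochondrial. The strongest lay in the coding sequence of the cytochrome b gene CYTB (signal 3541, M 4602 to 4878), with 1682 in replicate 1 and 1798 in replicate 2. Then came peaks in coding sequence whose nearest starts were those of tRNA-Ala (2386), ND5 (2026), COX1 (1582) and ATP6 (1134). The other mitochondrial peaks among the 20 ranged from 340.0 to 788.9 and had their nearest starts at tRNA-Leu, ATP6, COX3, tRNA-Asn, COX1, tRNA-Cys, s-rRNA, tRNA-His, l-rRNA, ND3 and ND2. The remaining peaks of the 20 were nuclear, ZK994.7 and an intergenic peak on IV at 15895993 to 15896111 with a signal of 379.6, whose nearest start was the piRNA gene 21ur-15381 at 357 bp.

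The replicates shared their stronger regions. Of the 296 peaks of replicate 1, 160 (54.1%, 48.4 to 59.6) overlapped a peak of replicate 2 by at least 1 bp, against 6.40% with random placement (permutation p = 0.0002, the smallest possible). On nuclear chromosomes alone the share was 136 of 269 (50.6%), against 0.119% at random. Of the 136 peaks found in the replicate 1 list only, all but 21 overlapped a peak of the ranked list of replicate 2, and of the 128 in the replicate 2 list only, all but 9 overlapped one of replicate 1. These shares of 84.6% and 93% compare with 20.5% and 22.7% under random placement (permutation p = 0.0002 for both, the smallest possible), a test chosen after the data were seen. Signal ranks were only loosely related across peaks, which are not independent replicates: Spearman's rho was 0.224 over the 77932 peaks of the ranked list of both replicates and 0.404 over the 713 peaks of the conservative list. Without mitochondrial peaks it was 0.339. The median log2 ratio of replicate 2 to replicate 1 over the 77932 peaks was 0.30, and 77.8% of them were within 1 log2 unit of it. In the conservative list, whose peaks were selected for agreement between replicates, the median was 0.07 and the share 97.5%, with a Pearson correlation of log2 signals of 0.824, or 0.603 without mitochondrial peaks.

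Peaks found in 1 replicate list only included both mitochondrial and nuclear regions. Many were not particular to that replicate. The conservative list, selected for agreement between replicates, overlapped 93 of the 136 in the list of replicate 1 only and 97 of the 128 in that of replicate 2 only. In replicate 1 the strongest of all those in 1 list only lay at M 4288 to 4497 (signal 149.9, nearest start tRNA-Gln), M 5169 to 5378 (120.5, tRNA-Leu) and M 9441 to 9650 (117.2, tRNA-Asp). The tRNA-Leu peak had a signal of 44.9 in the ranked list of replicate 2 (percentile 99.2), and the tRNA-Asp peak overlapped a peak of the conservative list. In replicate 2 they were an intergenic region at IV 16458509 to 16458621 (192.0, nearest start the piRNA gene 21ur-9399), M 5016 to 5147 (137.1, tRNA-Leu) and IV 11026072 to 11026301 (85.1) at the noncoding RNA gene F36H1.17, which lies beside mir-51. Both nuclear peaks overlapped a peak of the conservative list. The F36H1.17 peak had a signal of 35.7 in the ranked list of replicate 1 (percentile 98.9).

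**Figure D4:**
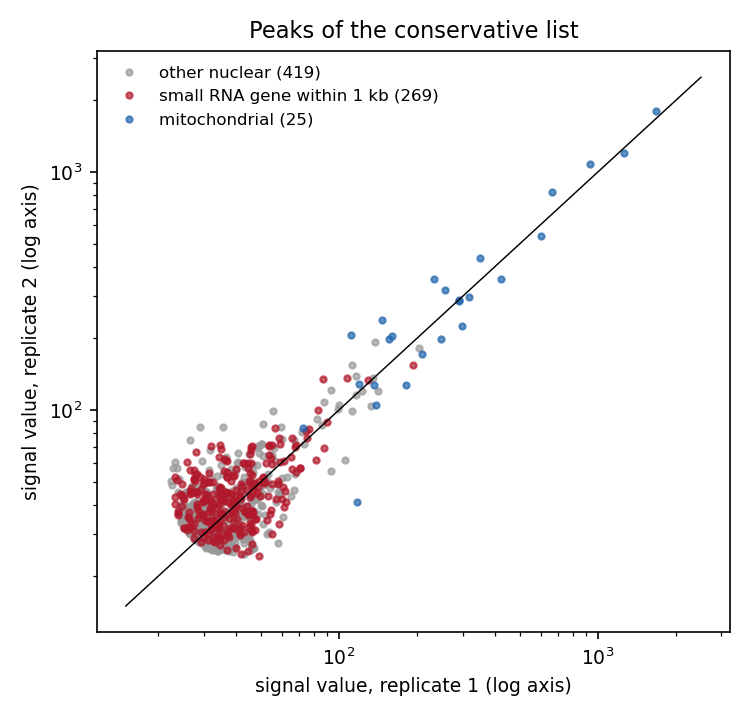
The authors' signal value in replicate 1 and in replicate 2 (both on log axes) for each of the 713 peaks of the conservative list, coloured by whether the peak is mitochondrial (25), within 1 kb of a small RNA gene (269) or elsewhere in the nucleus (419); the line marks equal values. Mitochondrial peaks reach 1682 and 1798, and Spearman's rho is 0.884 among them, 0.333 among peaks near small RNA genes and 0.281 among the others.

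Transgenes can raise the signal at the loci they copy. Within 20 kb of ceh-40 (X 12318126 to 12320777) the pooled list had 3 peaks, the strongest at X 12337922 to 12338161 28 bp from the start of the tRNA gene F17A2.t1, with a signal of 84.6 at percentile 99.7 of the ranked list. The ranked list had 39 peaks in that window, below the median of 50 in random windows of the same size on X. The median signal of these peaks was 24.1, above the 18.8 of the whole ranked list. It was also above the list median in the ranked list that goes with the conservative list (31.5 against 21.4). The same held in the ranked lists of replicate 1 (15.8 against 13.5) and replicate 2. Whether the median signal of other windows on X is raised as much was not tested. Within the whole ceh-40 gene and 1 kb on either side the strongest ranked peak had a signal of 42.3 (percentile 96.8). At unc-119 (III 10902641 to 10908935), the rescue gene of the strain, the ranked list of both replicates had no peak in the gene or within 1 kb of it, and that of replicate 1 had 4, the strongest with a signal of 17.3 at percentile 75.6.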

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

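The tests in this part were chosen after the results they bear on were seen.

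A signal appeared in ranked peaks that the comparisons above on thresholded lists do not use. Of 1014 peaks of the pooled ranked list at or past the IDR of the thresholded list, 147 (14.5%) are absent from the thresholded list. The strongest lies at X 15810957 to 15811186 with a signal of 2926 (1515 in replicate 1 and 1574 in replicate 2), 858 bp from the start of the pseudogene Y7A5A.11 and in intergenic sequence, and 10 of the 147 have a signal above that of every nuclear peak in the thresholded list. They fall into 64 clusters separated by more than 10 kb, 25 lie on X, 0 are mitochondrial, 8 lie within 1 kb of a small RNA gene, and 134 have a match in the ranked lists of both replicates. Why they were left out was not tested.

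Peaks were enriched at tRNA, snoRNA and snRNA genes, which with rRNA genes accounted for 302 of the 840 nuclear summits. A prediction written after the test was that binding of CEH-40 through its composite site would put the site at most of these summits. It was not met: 25 of 302 summit windows near small RNA genes held the site (8.28%, upper Wilson limit 11.9). Flanking windows held it more often (14.2%), but their GC content was lower (36.5% against 45.3%). Against shuffled sequence (5.96%) the difference was open (exact McNemar p = 0.337). Peaks need not hold an exact match to the site, and the 2 controls go opposite ways. The test therefore cannot exclude binding through the site. Reads shared between near-identical copies are argued against as the whole cause at tRNA genes. Of 53 tRNA genes of single-copy sequence with no other tRNA gene within 2 kb, 12 had a peak (22.6%, 13.5 to 35.5). Single-copy was judged by the median count of a gene's 31-mers in the genome, so parts of these genes can still recur elsewhere. Multi-copy genes had a peak more often (39.3%, Fisher's exact p = 0.0206), so shared reads may add to the pattern. Signal that follows strong transcription at any gene stays open, and transcription was not measured here. Ribosomal protein genes away from small RNA genes had peaks at 41%. Translation factor genes had them at 0 of 37, which says little, since other protein-coding genes had them at 1.94%. In the ranked list, with no genes left out for nearby small RNA genes, translation factors were above random lists (median 33.2, permutation adjusted p = 0.0013). Binding of CEH-40 to these genes through other proteins was not tested.

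The excess of peaks on X lies at its tRNA genes, since the share of summits on X fell to 11.9% without the summits near tRNA genes, but the number of these genes is not enough for it, as 56.5% of them had a peak against 35.7% of tRNA genes on the other nuclear chromosomes. Set against the 17.7% of the genome length, the same summits, with an upper limit of 14.6%, argue against a higher background over X as the whole cause. Their interval includes the 13.7% expected from protein-coding genes, so set against gene content they cannot tell. In addition, 19.1% of the ranked peaks short of the threshold lay on X, above its length share (exact binomial p = 1.19e-31). A contribution from background therefore stays open. Extra copies of the ceh-40 locus, which is on X, are argued against too, because X still held 22.9% of the nuclear summits without the 3 near ceh-40 (exact binomial p = 0.000113). No biological explanation was tested.

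The peaks on the mitochondrial genome are not explained by nuclear copies of mitochondrial DNA, as 0.0% of the 5215 31-mers in these peaks occur on the nuclear chromosomes. Whether they hold PBC-Hox sites more often than other mitochondrial sequence cannot be told apart from chance with 26 windows, of which 2 held the site (7.69%, against 13.5% of random windows, permutation p = 0.592). Many copies of mitochondrial DNA in the libraries may give signal over the whole molecule, and ranked peaks cover 43.4% of it against 24.5% of the nuclear genome, but read counts of the libraries and of the control, which would decide, were not used here. No biological explanation was tested.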

How the results depend on the processing

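Of 74 alternatives over 10 results, 8 change no peak and test nothing. Of the other 66, 45 kept the direction and the side of the threshold, stayed within the spread or, for counts, moved by no more than a set factor. Falls from 6 gene lists to 4 or 5 are within that factor and are among the 45, although single lists lost their call. Chosen after the data were seen are the IDR limit of 0.001, replicate 2 against replicate 1, sets without mitochondrial, tRNA or small RNA summits (except the planned rank correlation without mitochondrial and transgene loci), sets without piRNA genes, ranked peaks short of the threshold, the conservative list for rank correlation, and all those at the transgene loci. The overlap of the replicates (49.3% to 62.2%) and the share of summits near a TSS (34.8% to 79.2%) passed under every alternative run. For the results below the cause was not tested. Set against its share of the genome length, the share on X reversed to 11.9% without summits near tRNA genes and to 13.4% without those near any small RNA gene. The shortfall of PBC-Hox sites no longer passed against shuffled sequence (8.08% against 9.82%, exact McNemar p = 0.218), at the IDR limit of 0.001 (8.94% of 246 windows against 14.2% of flanks, exact p = 0.0984) and in the single-replicate lists (8.74% to 10.5% against 12.9% to 15.6%); the last sets have fewer windows than the 866 of the main one. The count of enriched 6-mers moved from 335 to 93 against shuffled sequence, 104 at the IDR limit of 0.001, 102 to 116 in the single-replicate lists, and 77 without both mitochondrial summits and those near small RNA genes (344 without mitochondrial summits alone). Sets with fewer peaks have less power. The difference in TSS share between stronger and weaker peaks fell to 3.74 points with a 1000 bp window, 5.88 at the IDR limit of 0.001, 1.49 without mitochondrial summits and those near small RNA genes, and 2.30 to 6.76 in the single-replicate lists. The number of gene lists above other genes rose from 6 to 11 with ranked-list signal and was 4 in each single-replicate list and at the IDR limit of 0.001. Spearman's rho moved to 0.424 at an IDR of at most 0.05, 0.404 in the conservative list and 0.339 there without mitochondrial peaks. The percentile of the strongest peak near ceh-40 was 98.7 to 99.5 in the single-replicate lists. No paired analysis was possible because there is only 1 group. Depth is unknown, so which peaks it limits cannot be stated.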

Other observations

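The tests in this part were chosen after the data were seen.

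Among other RNA genes, peaks were found at both genes for the RNAs of RNase P and RNase MRP (rpr-1 and mrpr-1), at 3 of 5 genes named as srpr, and at 10 of 18 genes for the SL2 spliced leader, which is added to the downstream transcripts of operons. None of the 12 annotated SL1 genes, which encode the other spliced leader, had a peak of the pooled list, but 4 had a ranked peak past the same threshold within 1 kb that this list does not hold, so the families cannot be contrasted on this list. The left-out peaks whose nearest start was that of an rRNA or SL1 gene all lay between V 17122148 and 17128297. This count and that of the nuclear rRNA genes with left-out peaks may therefore rest on the same peaks. The SL2 genes with a peak were reached by 9 peaks, with sls-2.4 first (signal 139.8, summit past the end of the gene), and sls-2.1 had a signal of 93.8 with its summit 14 bp from the start.

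Peaks at tRNA genes were spread over the amino acids. Of 20 isotypes with at least 5 nuclear genes, none differed from the other tRNA genes after adjustment (Fisher's exact test, Benjamini-Hochberg), and 3 did at an unadjusted p under 0.05: tRNA-Lys (29 of 46, 63%, p = 0.0133, adjusted p = 0.161), tRNA-Ala (22 of 34, 64.7%) and tRNA-Cys (10 of 13, 76.9%). An exact match to the B box sequence GGTTCGANNCC made no detectable difference, with a peak at 174 of 394 tRNA genes that have the match (44.2%) and at 102 of 218 that depart from it (46.8%, Fisher's exact p = 0.553).

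Several of the strongest nuclear peaks outside the rule had a protein-coding gene as their nearest gene. The gene pck-2, which encodes a phosphoenolpyruvate carboxykinase, had a signal of 237.8 at I 7868992 to 7869247, with the summit in its UTR 13 bp from the start. An intron of tir-1, a gene of innate immunity, had a pair of peaks with signals of 236.7 (III 3897579 to 3897696) and 224.1 (III 3897261 to 3897358). The gene F44E5.4 had 206.4 at II 11759303 to 11759542, 112 bp upstream of its start, mog-4 had 195.5 at II 14561836 to 14561901, and cdc-48.1, an AAA ATPase of protein quality control, had 160.6 at II 10563526 to 10563616, with the start of the snoRNA gene C06A1.9 500 bp away.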
